A study of Homo sapiens with 12 samples.

How the data were processed

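RNA from MCF7 cells was sequenced in 12 libraries. MCF7 is an established line of luminal, estrogen receptor positive breast cancer cells. Per the labels, its GATA3 gene had been knocked out and 4 forms of the GATA3 protein were then expressed stably from lentivirus, in 3 libraries each. GATA3 is a transcription factor of the luminal lineage that binds DNA through 2 zinc fingers. WT is the unaltered protein. In 2R-A, 2 neighbouring arginines of zinc finger 2 were replaced by alanine. The labels name the remaining forms X308 and R330 and do not say what was changed in them. No parental cells and no cells with an empty vector were sequenced, so WT was the reference for each mutant. The labels do not say whether the 3 libraries of a group came from separate cultures or separate infections, and all libraries of a group share one construct. Poly-A RNA was selected and a stranded library was prepared. The batch tag of the labels differs from the replicate number in the title for 5 libraries, and each of its 3 values holds 1 library of each group.

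The authors deposited 1 table of 61806 Ensembl genes, of which 41389 carried a symbol, with whole-number counts per gene and library, the exonic size of each gene, and gene ontology and pathway terms. The authors also deposited FPKM, which were recomputed from the counts as count per exonic size and library total and differed from that by at most 0.00500. The submitters' processing notes name RSEM without a version. The aligner, the strand setting and the genome build are not given in the sources used here. Of the gene IDs, 58254 were also in GENCODE release 29 for build GRCh38, and 71.52% of these had the same chromosome, start and end there. Coordinates are those of the deposited table. Library totals lay between 15813036 and 20675287 counts. Floors and intervals below cover counting error only, because the reads carry no molecular identifiers in these files.

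Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 16852 genes, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries, leaving 8 residual degrees of freedom. The 6 pairs of groups were compared, and 1 further test asked for any difference among the 4 groups. P-values were adjusted over the genes tested by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. A 2-fold change means an absolute log2 fold change of at least 1. Unless another tool is named, adjusted p and fold changes are from this edgeR model, errors of log2 fold changes are standard errors, and other errors are standard deviations. Levels are given as CPM, the count in relation to the TMM-scaled library total. Each test compares 3 libraries with 3, so p-values measure only the spread between these libraries. On simulated data of the same size, 82.1% of genes changed 2-fold and 56.1% of genes changed 1.41-fold were recovered, and 5% of the calls were genes that had not been changed.

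The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named GATA3, ESR1, FOXA1, PGR, TFF1, CDH1 and VIM in every comparison with WT. To these it added the 8 largest rises and 8 largest falls among called genes with a symbol that changed at least 2-fold, had a mean FPKM of at least 1 in the higher group and did not overlap between groups, and up to 2 members of each list. Between mutants it took 5 rises and 5 falls, and for genes called in all 3 comparisons with WT 5 in each direction. The 24 lists tested were luminal identity, estrogen response, basal and myoepithelial genes, mesenchymal genes, epithelial adhesion, matrix proteases and inhibitors, mitosis, DNA replication and G1/S, interferon response, antigen presentation, NF-kB and inflammatory genes, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress, p53 targets, immediate early genes, heat shock, GATA family and cofactors, neuronal and developmental genes, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and fibroblast and endothelial markers. A list of leukocyte markers had only 2 measured members and was not tested. Lists were compared with all other genes by camera (limma 3.58.1) with its preset inter-gene correlation of 0.01 and again with the correlation estimated from the libraries, each adjusted over the lists. For ontology and pathway terms of 10 to 300 genes, called genes of each direction were tested by a one-sided hypergeometric test against the 13781 tested genes that carried a term.

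A correction was added after the data had been seen, because fold changes of X308 and R330 followed transcript length and GC content. For each library, a smooth surface over log2 transcript length and GC content was fitted to the protein-coding genes with mgcv 1.9.3 and entered edgeR as an offset. Length and GC content were taken from the longest coding transcript of a gene, or its longest transcript, and were known for 97.8% of the genes tested, which left 16476 genes. Calls, fold changes and medians named corrected come from that model. For camera after the correction, the surface was subtracted again from log2 CPM that already carried the offset. The trend was thus removed more than once. Those tests also took log2 CPM, where camera before the correction took counts. Their results are named overcorrected, and a pass or a loss there cannot tell how the list stands with corrected fold changes. On simulated data with a linear trend put in from the same length and GC values, the correction reduced the calls from 11493 to 423. Of genes changed 2-fold, 85.4% were recovered. The simulation does not show that the trend of the data is removed as well, where 11094 genes were called in X308 after the correction. The correction also removes any true change that happens to follow length or GC content.

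Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, only the 2 groups compared, a block for the batch tag or for the replicate number, leaving out each library, and limma on log2(FPKM + 1) with other pseudocounts, filters and scalings. A block was not part of the test, because correlations of the residual profiles of libraries that share a batch tag lay between -0.0332 and 0.0547, and those that share a replicate number between -0.0332 and 0.0685. Scaling by library totals in place of TMM moved the median log2 difference of all genes by -0.19 in X308 and by -0.20 in R330 against WT, and by less than 0.1 in 2R-A. Genes that overlap other genes, antisense genes, pseudogenes and near-identical paralogs may share reads, which the table cannot resolve. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.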

Results

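The data are counts of 61806 genes in 12 libraries of MCF7 cells that lack their own GATA3 and express WT, 2R-A, X308 or R330 GATA3, with 3 libraries per form. The series title concerns regulation of the transcriptome through a phase separation that zinc finger 2 modulates, and the design compared the 4 forms with each other. Genes with a count numbered 25709 ± 480 (n = 3) in WT, 25589 ± 312 in 2R-A, 24473 ± 207 in X308 and 24004 ± 536 in R330, from totals between 15813036 and 20675287 counts. Libraries of a group correlated with r between 0.992 and 0.993 across genes, which are not independent replicates. The first principal component held 83.2% of the variance and separated WT and 2R-A from X308 and R330. Any difference among the 4 forms was called for 13936 of 16852 genes, or 82.7%.

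GATA3 messages (chromosome 10, 8045378 to 8075198, plus strand) were abundant in all 4 groups. The level was 772 ± 20.3 CPM in WT, 967 ± 15.5 in 2R-A, 829 ± 20.9 in X308 and 888 ± 53.6 in R330 (n = 3 each). Against WT the log2 fold change was 0.32 ± 0.04 in 2R-A (adjusted p = 2.5e-06), 0.10 ± 0.04 in X308 (adjusted p = 0.0222) and 0.20 ± 0.04 in R330 (adjusted p = 4.2e-05), each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The rise in 2R-A held under every alternative. In X308 the sign depended on the processing. GATA3 was called lower after the length and GC correction (-0.09, adjusted p = 0.0120), on TPM, with quantile normalization and with library totals. The call as higher was lost without WT replicate 2 (0.10) or WT replicate 3 (0.09). In R330 the corrected value was 0.04 and not called, and the sign was negative under limma on FPKM, on TPM, with quantile normalization and with library totals. It was called lower there on TPM and with quantile normalization. A gene-level table cannot tell reads of the expressed construct from reads of the edited gene.

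**Figure D1:**
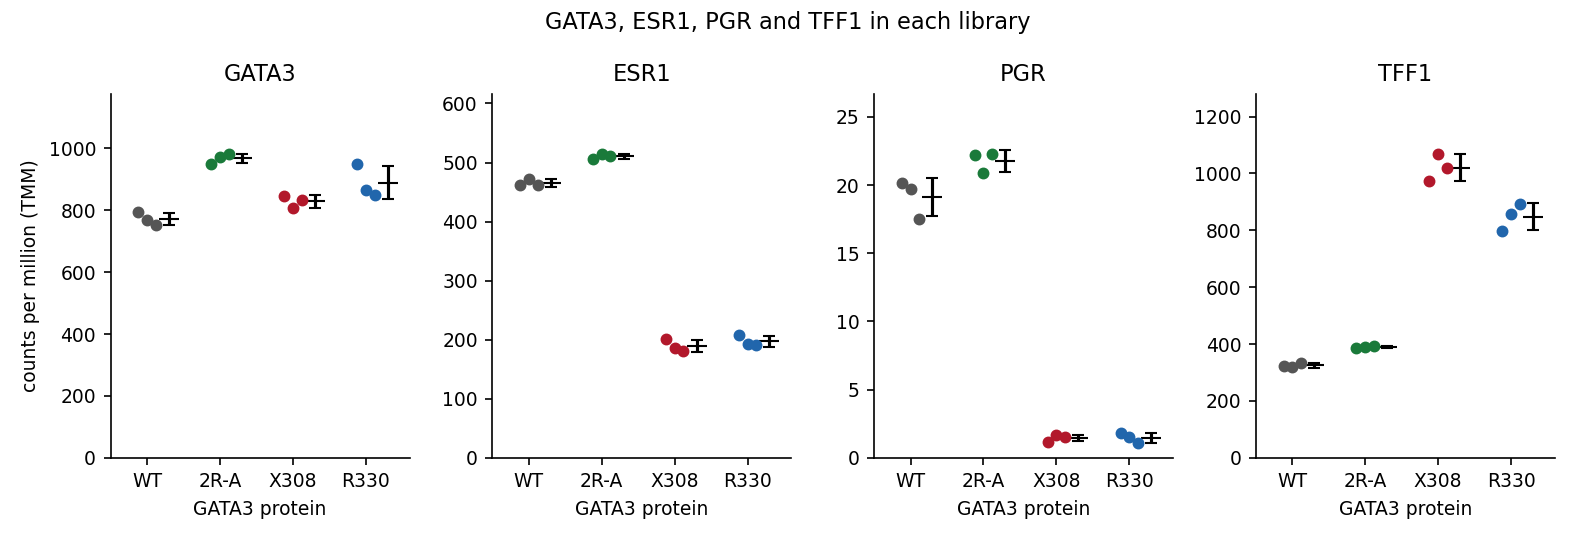
CPM (linear axes from 0) of GATA3, ESR1, PGR and TFF1 in each library by GATA3 form; points are libraries and the black mark beside them is the mean with its standard deviation (n = 3). PGR lay near 19.1 CPM in WT and near 1.46 CPM in X308 and R330, where ESR1 was also lower, while GATA3 was present in all 4 groups.

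The comparison of 2R-A with WT asks what the loss of 2 arginines of zinc finger 2 does to transcription. Interferon-induced antiviral genes made up the largest rises. IFI44L (chromosome 1, 78619902 to 78646145) went from 1.48 ± 0.0490 to 13.6 ± 1.14 CPM, a log2 fold change of 3.20 ± 0.14 (adjusted p = 4.03e-17). Its neighbour IFI44 rose by 2.89 ± 0.12, IFI27 by 2.72 ± 0.09, OAS2, a sensor of double-stranded RNA, by 2.54 ± 0.08, IFI6 by 2.28 ± 0.13, IFIT1, which binds viral RNA, by 2.04 ± 0.10 and DDX60 by 1.62 ± 0.11. CSTA, a cysteine protease inhibitor, rose by 1.67 ± 0.28. No gene that fell met the rule for the largest falls. In all, 302 genes rose and 206 fell, and 29 rose and 6 fell at least 2-fold.

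Of 40 measured interferon-response genes, 32 rose, 0 fell and 8 did not pass, with a median log2 fold change of 1.03 (camera adjusted p = 2.42e-285, and 1.88e-07 with an estimated correlation), and 35 rose when adjusted over the list alone. Of 20 antigen presentation genes 3 rose and 9 rose when adjusted over the list alone (camera adjusted p = 7.34e-06), among them B2M, the light chain of MHC class I, by 0.22 ± 0.04. The chemokine CCL5 rose by 1.10 ± 0.22 although the NF-kB and inflammatory list was lower as a whole, with 1 of 21 members higher and 4 lower (adjusted over the list alone 1 and 6; camera adjusted p = 0.00953), including CCL2 at -0.66 ± 0.08.

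Luminal identity genes were also higher in 2R-A. Of 29 measured, 12 rose and 1 fell, and 14 and 1 when adjusted over the list alone (camera adjusted p = 2.11e-16, and 9.88e-04 with an estimated correlation). SLC39A6, a zinc transporter, rose by 0.40 ± 0.04 and ANXA9 by 0.44 ± 0.06. Estrogen response genes split, with 8 of 40 higher and 4 lower (adjusted over the list alone 11 and 4). Their camera adjusted p was 0.0447, and the call was lost with adjusted p = 0.356 with an estimated correlation. TFF1, an estrogen-induced secreted peptide, rose by 0.26 ± 0.04, and AREG, a ligand of the EGF receptor, changed by -0.34 ± 0.05. The changes of ESR1 (0.13 ± 0.04, adjusted p = 0.0662), FOXA1 (0.10 ± 0.04, adjusted p = 0.246), PGR (0.19 ± 0.08, adjusted p = 0.268) and VIM (-0.04 ± 0.15, adjusted p = 0.943) did not pass. CDH1 passed at 0.14 ± 0.04 (adjusted p = 0.0398) in the full set and in no fit that left out a WT or a 2R-A library, where it lay between 0.11 and 0.15.

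A further 7 lists passed in 2R-A with the preset correlation. Other splits of the same 6 libraries passed up to 9 lists, against 12 in the real one, so a pass with the preset correlation alone is uncertain. Where no value with an estimated correlation is given below, the list passed with it too. Hypoxia and glycolysis genes were higher (8 of 32 rose, 0 fell; 11 and 0 adjusted over the list alone; camera adjusted p = 6.5e-08), with ALDOC at 0.46 ± 0.06 and ENO2 at 0.32 ± 0.06, both glycolytic enzymes. Replication-dependent histone messages, which normally lack a poly-A tail, were higher (5 of 19 rose; 6 adjusted over the list alone; camera adjusted p = 6.53e-06), with H2BC5 at 0.51 ± 0.10. Cholesterol synthesis (0 of 24 members past; 0 adjusted over the list alone; camera adjusted p = 0.00198) and mitochondrially encoded genes (0 of 13; 0 adjusted over the list alone; camera adjusted p = 0.00527, and adjusted p = 0.36 with an estimated correlation) were higher only as sets. DNA replication and G1/S genes were lower (2 of 40 fell; 10 adjusted over the list alone; camera adjusted p = 6.5e-08), including RRM2, a subunit of ribonucleotide reductase, at -0.23 ± 0.04. Cytosolic ribosomal protein genes were lower (3 of 54 fell; 11 adjusted over the list alone; camera adjusted p = 6.41e-08, and adjusted p = 0.374 with an estimated correlation). The unfolded protein and integrated stress list was lower (4 of 30 fell; 1 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.126 with an estimated correlation), with the cystine transporter SLC7A11 at -0.55 ± 0.07 and PSAT1, of serine synthesis, at -0.38 ± 0.06.

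The other 12 lists did not pass in 2R-A as tested. Among their members 3 of 35 epithelial adhesion genes rose, including TJP3 at 0.23 ± 0.05, 4 of 18 heat shock genes rose, including DNAJB1 at 0.24 ± 0.04, and 3 of 26 p53 targets rose and 1 fell. Of 22 immediate early genes 3 rose and 2 fell, 1 of 20 basal and myoepithelial genes rose, TIMP3 fell by 0.89 ± 0.17 as 1 of 21 matrix proteases and inhibitors, and 1 of 15 GATA family and cofactor genes fell. No member passed among 16 mesenchymal, 35 mitosis, 14 neuronal and developmental, and 4 fibroblast and endothelial genes, and 1 rose and 1 fell among 40 oxidative phosphorylation genes. Adjusted over the list alone, 8 rose and 1 fell for epithelial adhesion, 5 rose for mitosis, 4 rose and 1 fell for heat shock, 3 rose and 1 fell for GATA family and cofactors, 1 rose and 1 fell for basal, mesenchymal and matrix protease genes, 1 fell for fibroblast and endothelial genes, and the other counts stayed the same. By annotation terms, 37 of 140 genes of the defense response to virus were among the risen (adjusted p = 3.33e-27, hypergeometric test), and 12 of 162 genes of rRNA processing among the fallen (adjusted p = 0.0139). After the correction 4 of 35 mitosis genes were higher, and the list passed overcorrected camera (adjusted p = 0.0011, and 0.29 with an estimated correlation). The estrogen response and the unfolded protein and integrated stress lists did not (overcorrected camera adjusted p = 0.163 and 0.0569). Their medians were 0.05 and -0.04 after the correction and 0.04 and -0.04 before.

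The total of 508 genes in 2R-A moved with single libraries. It was 263 without WT replicate 1, 282 without WT replicate 2, 325 without 2R-A replicate 1, 284 without 2R-A replicate 2, 259 without 2R-A replicate 3 and 828 without R330 replicate 1, which is in neither group. With a block for the batch tag it was 643, and after the length and GC correction 936, of which 506 were the same genes in the same direction.

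**Figure D2:**
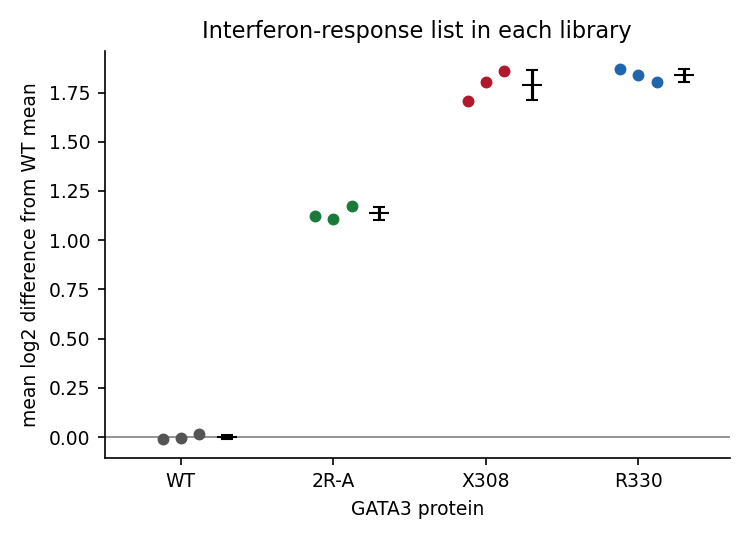
Mean log2 difference of the interferon-response list from the WT mean in each library, by GATA3 form; points are libraries and the black mark is the mean with its standard deviation (n = 3). The 2R-A libraries averaged 1.14, the X308 libraries 1.79 and the R330 libraries 1.84, without overlap with WT.

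X308 and R330 were each compared with WT to ask what these 2 forms do in place of the unaltered protein, and their profiles were close to each other. Interferon-induced genes were again among the largest rises. IFI6 went from 5.58 ± 0.598 CPM in WT to 175 ± 15.5 in X308 and 171 ± 21.8 in R330, log2 fold changes of 4.98 ± 0.10 and 4.94 ± 0.10 (corrected 3.75 and 3.76). ISG15, a ubiquitin-like antiviral protein, rose by 4.53 ± 0.12 and 4.56 ± 0.12 (corrected 3.01 and 3.13). CEACAM6, a cell adhesion glycoprotein, rose by 5.11 ± 0.17 and 4.31 ± 0.19 (corrected 5.17 and 4.38). The progesterone receptor gene PGR (chromosome 11, 101029624 to 101129813, minus strand) fell from 19.1 ± 1.38 to 1.46 ± 0.249 and 1.46 ± 0.364 CPM, log2 fold changes of -3.70 ± 0.14 and -3.68 ± 0.14 (corrected -2.42 and -2.41).

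The fold changes of both forms followed transcript length and GC content. Across 12894 protein-coding genes, Spearman's rho of log2 fold change with transcript length was -0.632 in X308 and -0.629 in R330, and with GC content 0.595 and 0.572, against 0.00196 and 0.128 in 2R-A. Both properties together held 51.8% and 49.6% of the variance of the fold changes, against 0.697% in 2R-A. With coding genes in 4 equal bins of length, counts of the longest bin over those of the shortest were 0.915 ± 0.0103 in WT, 0.899 ± 0.0105 in 2R-A, 0.315 ± 0.0128 in X308 and 0.322 ± 0.0166 in R330. MT-ND4L and MT-ND4 are read from a single mitochondrial message, and counts of the first per 100 of the second were 12.1 ± 0.236, 11.2 ± 0.869, 2.47 ± 0.119 and 2.70 ± 0.318 in the same order. MT-ATP8 per 100 MT-ATP6, also a shared message, gave 21.8 ± 3.30, 23.3 ± 1.30, 7.82 ± 0.638 and 8.87 ± 1.08. In both pairs the shorter frame was the one that fell, against the direction of the trend across coding genes. Because of that trend, corrected values stand beside the log2 fold changes of these forms.

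**Figure D3:**
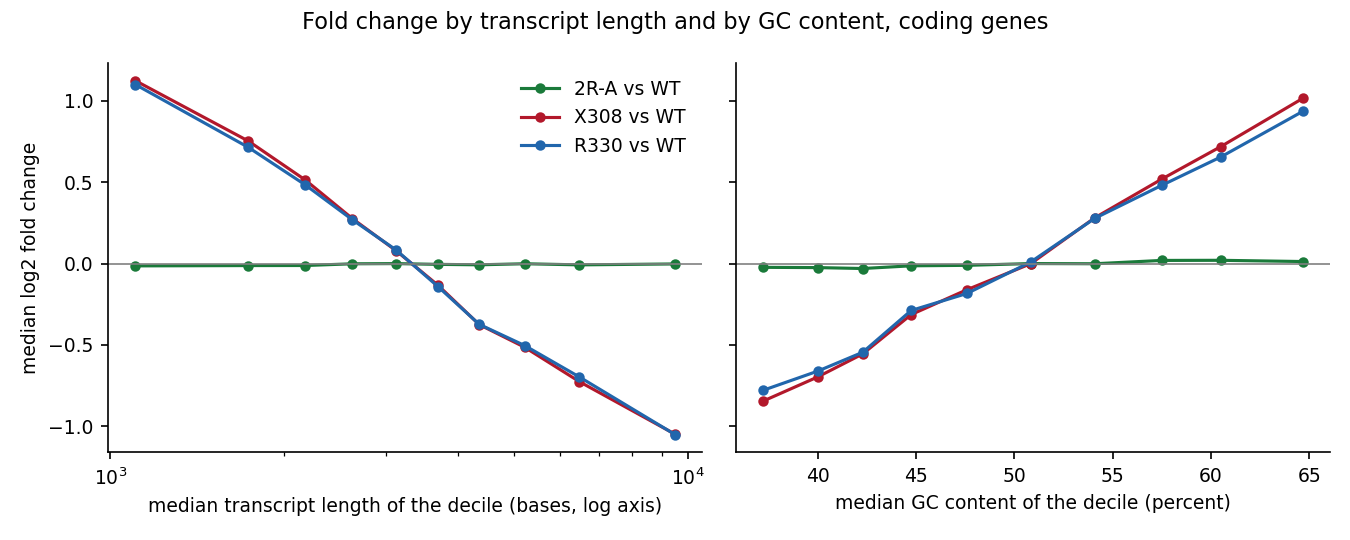
Median log2 fold change against WT (vertical axis) of protein-coding genes in 10 bins of transcript length (left, log axis, bases) and of GC content (right, percent); each point is a bin and each line a GATA3 form. X308 and R330 fall with length and rise with GC content, and 2R-A stays near 0.

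In X308 6553 genes rose and 6664 fell, 2689 and 3034 of them at least 2-fold, and in R330 6378 rose and 6755 fell, 2486 and 3097 at least 2-fold. With a block for the batch tag the totals of 13217 and 13133 were 13243 and 13158. After the correction 4908 rose and 6186 fell in X308, and 5057 rose and 6050 fell in R330, with 7837 and 8000 genes called in the same direction before and after. The share that rose, 49.6% and 48.6%, was 41.1% and 39.2% with library totals in place of TMM, so the split in direction depends on scaling. It was 28.1% and 27.0% when FPKM were rescaled to equal sums (TPM), and 39.6% and 37.5% with FPKM and no filter, which also change the tool and the genes tested.

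Of 40 interferon-response genes 37 rose and 1 fell in X308 and 36 rose and 1 fell in R330, the same counts when adjusted over the list alone. The medians were 1.91 and 1.98 (camera adjusted p = 4.99e-17 and 3.98e-19, and 0.0175 and 0.0101 with an estimated correlation). After the correction 36 rose and 0 fell in X308 with a median of 1.64. For R330, 37 rose and 1 fell, with a median of 1.67. The list passed overcorrected camera in both (adjusted p = 2.24e-08 and 8.47e-09). With an estimated correlation it passed there in R330 (adjusted p = 0.0484) and not in X308 (adjusted p = 0.056). IFI44L rose by 3.81 ± 0.13 and 3.79 ± 0.13 (corrected 4.79 and 4.73) and IFI27 by 4.52 ± 0.08 and 4.54 ± 0.08 (corrected 3.17 and 3.24). Antigen presentation genes rose in both forms, 16 of 20 with 2 lower in each, the same adjusted over the list alone (camera adjusted p = 4.05e-05 and 1.14e-04, and 0.0175 and 0.0193 with an estimated correlation). The MHC class I gene HLA-A rose by 2.10 ± 0.06 and 2.14 ± 0.06 (corrected 1.26 and 1.35). After the correction 16 members were called higher in each form, with medians of 0.94 and 0.92, against 1.40 and 1.28 before. The list did not pass overcorrected camera (adjusted p = 0.212 and 0.192).

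Hormone-response genes went both ways in X308 and R330. Of 40 estrogen response genes 16 rose and 23 fell in X308 and 14 rose and 24 fell in R330, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.157 and 0.0635). ESR1, which encodes estrogen receptor alpha, fell by 1.30 ± 0.04 and 1.23 ± 0.04 (corrected -0.60 and -0.53). NRIP1, a corepressor of nuclear receptors, fell by 2.70 ± 0.07 and 2.57 ± 0.07 (corrected -1.61 and -1.51). TFF1 rose by 1.65 ± 0.04 and 1.38 ± 0.04 (corrected 0.30 and 0.05, the latter not called). Of 29 luminal identity genes 14 rose and 14 fell in X308 and 14 rose and 15 fell in R330, the same adjusted over the list alone (camera adjusted p = 0.857 and 0.843). The prolactin receptor gene PRLR fell by 2.19 ± 0.04 and 2.27 ± 0.04 (corrected -0.89 and -0.999), and FOXA1, a pioneer factor of the luminal program, by 0.25 ± 0.04 and 0.27 ± 0.04 (corrected -0.39 and -0.38). Among 15 GATA family and cofactor genes 7 rose and 7 fell in each form, with the acetyltransferase gene EP300 at -2.20 ± 0.06 and -2.17 ± 0.06 (corrected -1.52 and -1.48).

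Some genes of basal and smooth muscle cells rose in X308 and R330. KRT17, a basal keratin, rose by 3.68 ± 0.27 and 3.61 ± 0.27 (corrected 2.58 and 2.59), ACTA2, smooth muscle actin, by 2.22 ± 0.16 and 2.05 ± 0.16 (corrected 1.44 and 1.31), and ACTG2, a further smooth muscle actin, by 3.70 ± 0.12 in X308 (corrected 3.22). Of 20 basal and myoepithelial genes 9 rose and 3 fell in X308 and 10 rose and 2 fell in R330 (adjusted over the list alone 9 and 3, and 9 and 2), and the list did not pass (camera adjusted p = 0.465 and 0.493). Of 16 mesenchymal genes 6 rose and 5 fell in X308 and 6 rose and 7 fell in R330 (camera adjusted p = 0.543 and 0.62), with TGFBI, a matrix protein, up by 3.40 ± 0.17 and 3.20 ± 0.18 (corrected 3.12 and 2.95). VIM did not pass in X308 (-0.01 ± 0.15) or R330 (-0.32 ± 0.16), though its corrected values of -0.54 and -0.81 did, as did the R330 value without WT replicate 1 (-0.44). Of 35 epithelial adhesion genes 18 rose and 15 fell in each form (camera adjusted p = 0.537 and 0.544), with the desmosomal genes DSG2 at -1.84 ± 0.05 and -1.77 ± 0.05 (corrected -1.05 and -0.97) and DSP at -1.53 ± 0.04 and -1.62 ± 0.04 (corrected -0.64 and -0.73). CDH1, or E-cadherin, was at -0.51 ± 0.04 and -0.46 ± 0.04 (corrected -0.11 and -0.04, the latter not called).

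Ribosomal protein and oxidative phosphorylation genes rose almost throughout. All 54 measured cytosolic ribosomal protein genes rose in both forms, also when adjusted over the list alone, with medians of 1.28 and 1.26 (camera adjusted p = 2.88e-37 and 3.07e-38, and adjusted p = 0.159 and 0.142 with an estimated correlation). RPLP1 rose by 1.90 ± 0.05 and 1.85 ± 0.05 (corrected 1.23 and 1.21). Of 40 nuclear-encoded oxidative phosphorylation genes 39 rose and 1 fell in each, the same adjusted over the list alone (camera adjusted p = 1.59e-16 and 1.72e-19, and adjusted p = 0.159 and 0.136 with an estimated correlation), with COX4I1 at 1.47 ± 0.05 and 1.52 ± 0.05 (corrected 0.81 and 0.90). Their median transcript lengths were 1150 and 1660 bases, in the range where the median coding gene was higher in both forms. Neither list passed overcorrected camera, where the ribosomal list pointed lower although its corrected medians were above 0. Corrected, 42 of 54 ribosomal protein genes rose and 4 fell in X308 and 44 rose and 3 fell in R330 (medians 0.55 and 0.55). Of 40 oxidative phosphorylation genes 35 and 39 rose with 0 lower (medians 0.44 and 0.57, against 1.08 and 1.15 before). The pathway term of oxidative phosphorylation passed with corrected calls, with 86 and 93 of 164 genes higher (adjusted p = 5.67e-04 and 4.83e-06, hypergeometric test). By annotation terms of X308 and R330, 166 of 207 genes of cytoplasmic translation were among the risen in each (adjusted p = 1.45e-28 and 1.87e-29, hypergeometric test), and 124 and 121 of 192 genes of protein kinase activity among the fallen (adjusted p = 3.4e-07 and 6.53e-06). These term values are before the correction. With corrected calls, terms past among the fallen went from 79 and 78 to 15 and 2, and among the risen from 58 and 66 to 26 and 34. The unfolded protein and integrated stress list rose, 18 of 30 with 6 lower in X308 and 21 with 7 lower in R330, the same adjusted over the list alone (camera adjusted p = 0.0101 and 0.00609, and adjusted p = 0.159 and 0.142 with an estimated correlation), with PHGDH, of serine synthesis, at 1.19 ± 0.04 and 1.09 ± 0.04 (corrected 0.59 and 0.55). The list did not pass overcorrected camera (adjusted p = 0.888 and 0.715), and its corrected medians were 0.19 and 0.28, against 0.59 and 0.49 before. Of 19 replication-dependent histone genes 9 rose and 1 fell in X308 and 10 rose and 1 fell in R330 (8 and 1 in each adjusted over the list alone; camera adjusted p = 0.37 and 0.493). Corrected, 4 of 18 rose and 6 fell, and 4 rose and 7 fell (overcorrected camera adjusted p = 0.266 and 0.182). Of 13 mitochondrially encoded genes 9 rose and 4 fell in each (camera adjusted p = 0.231 and 0.211). After the correction 10 and 11 fell and 0 rose (overcorrected camera adjusted p = 8.17e-04 and 4.24e-04, and 0.616 and 0.551 with an estimated correlation).

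The cell cycle and stress lists had members on both sides and did not pass as tested, and adjusted over the list alone the counts below stayed the same except for 7 and 15 in the cholesterol list of X308. Of 35 mitosis genes 14 rose and 19 fell in each form (camera adjusted p = 0.148 and 0.419), with ASPM, a spindle protein with a long message, at -2.17 ± 0.05 and -1.96 ± 0.05 (corrected -0.86 and -0.69). The medians of this list changed sign with the correction, from -0.22 to 0.05 in X308 and from -0.14 to 0.13 in R330. Corrected, 14 were up and 13 down in X308, and 18 up and 11 down in R330. The list passed overcorrected camera as higher (adjusted p = 8.17e-04 and 1.83e-04), but not with an estimated correlation (adjusted p = 0.616 and 0.482). Of 40 DNA replication and G1/S genes 16 rose and 21 fell in X308 and 18 rose and 18 fell in R330 (camera adjusted p = 0.857 and 0.493), with the licensing factor CDT1 at 1.60 ± 0.05 and 1.44 ± 0.05 (corrected 0.85 and 0.75). Of 26 p53 targets 13 rose and 9 fell, and 12 rose and 9 fell (camera adjusted p = 0.157 and 0.141), with CDKN1A, an inhibitor of cyclin-dependent kinases, at 1.94 ± 0.05 and 1.88 ± 0.05 (corrected 1.25 and 1.25). Of 24 cholesterol synthesis genes 7 rose and 14 fell in X308 and 9 rose and 14 fell in R330 (camera adjusted p = 0.205 and 0.316), with HMGCS1 at -1.85 ± 0.06 and -1.64 ± 0.06 (corrected -1.32 and -1.13). After the correction 18 of 24 members were lower in X308 (overcorrected camera adjusted p = 0.0227, and 0.149 with an estimated correlation).

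The remaining lists did not pass in either form. Of 22 immediate early genes 15 rose and 3 fell in X308 and 13 rose and 4 fell in R330 (camera adjusted p = 0.069 and 0.137), with JUNB, an AP-1 subunit, at 1.30 ± 0.05 in X308 (corrected 0.11). Of 18 heat shock genes 9 rose and 5 fell, and 12 rose and 5 fell (camera adjusted p = 0.231 and 0.0831), with HSPB1 at 1.80 ± 0.06 and 1.70 ± 0.06 (corrected 0.29 and 0.28). Of 32 hypoxia and glycolysis genes 18 rose and 9 fell in X308 (19 and 9 adjusted over the list alone) and 15 rose and 11 fell in R330 (camera adjusted p = 0.148 and 0.62). Of 21 matrix proteases and inhibitors 8 rose and 5 fell, and 9 rose and 6 fell, with the protease gene ADAM17 at -2.68 ± 0.10 and -2.63 ± 0.10 (corrected -2.06 and -2.03). Exons of FOXA1, RRM2, DNAJB1, CEACAM6, ACTA2, COX4I1, JUNB, ADAM17, CA9, ZBTB47-AS1 and MT-ND4L overlap exons of other genes, so reads of these genes are uncertain.

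**Figure D4:**
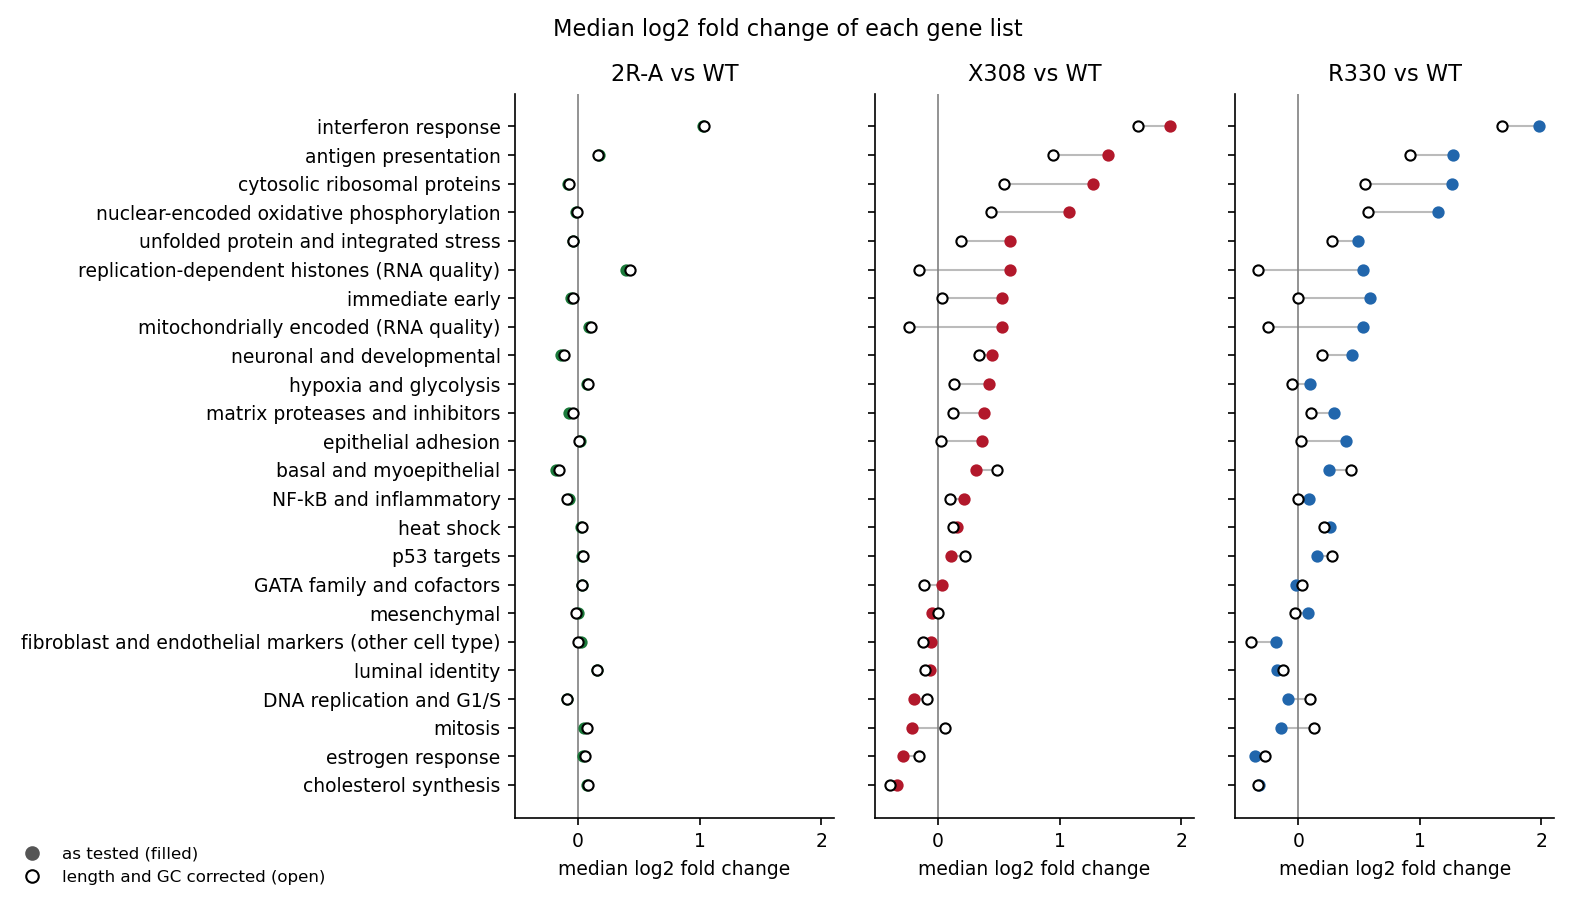
Median log2 fold change against WT (horizontal axis) of each of the 24 gene lists (vertical axis) in 2R-A, X308 and R330, with filled points as tested and open points after the length and GC correction. The interferon-response list had the highest median in all 3 panels, 1.03, 1.91 and 1.98 as tested.

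Among the largest falls were genes inside or opposite other genes that fell to near the detection limit. EBLN2 had 1.61 ± 0.435 CPM in WT and no count in X308, which makes it at least 29.3-fold lower against a floor of 3 counts over the group. ZBTB47-AS1 went from 5.19 ± 0.933 CPM to 0.0927 ± 0.115 in X308 and 0.0422 ± 0.0731 in R330, and NPTN-IT1 from 5.15 ± 0.448 to 0.0343 ± 0.0594 in R330. Such genes may share reads with the genes they overlap, so their own levels are uncertain. Of 282 non-coding genes inside introns of coding genes on the same strand, 72 fell at least 4-fold in X308, or 25.5% (95% exact Clopper-Pearson interval 20.5 to 31.0), against 150 of 1639 outside coding genes, or 9.15% (7.80 to 10.7).

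X308 and R330 were also compared with 2R-A, which asks how the forms differ from the arginine mutant. ACTG2 rose from 0.948 ± 0.166 CPM in 2R-A to 35.7 ± 4.36 in X308 and 33.6 ± 2.50 in R330, log2 fold changes of 5.22 ± 0.14 and 5.13 ± 0.14 (corrected 4.73 and 4.67). CEACAM6 rose by 4.79 ± 0.16 and 3.99 ± 0.18 (corrected 4.83 and 4.04), KRT17 by 3.88 ± 0.28 and 3.81 ± 0.28 (corrected 2.79 and 2.80), MESP1, a transcription factor of early mesoderm, by 4.38 ± 0.49 and 4.42 ± 0.49 (corrected 3.68 and 3.77), and PYDC1, a pyrin-domain protein, by 3.87 ± 0.59 and 3.89 ± 0.59 (corrected 2.51 and 2.62). Among the largest falls were again non-coding genes that fell to near 0, such as NPTN-IT1 in R330, at 0.0343 ± 0.0594 CPM against 4.62 ± 0.278. Of 16852 genes, 6511 rose and 6671 fell in X308, and 6320 rose and 6729 fell in R330. With a block for the batch tag the totals of 13182 and 13049 were 13213 and 13069. After the correction 10994 and 11032 were called. The share that rose, 49.4% and 48.4%, was 28.6% and 27.4% on TPM, and 37.5% in R330 with FPKM and no filter.

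The interferon-response list was higher than in 2R-A as well, with 25 of 40 members higher and 7 lower in X308 and 26 higher and 7 lower in R330, the same adjusted over the list alone. The medians were 0.67 and 0.91 (camera adjusted p = 5.15e-04 and 9.09e-05), and with an estimated correlation the calls were lost (adjusted p = 0.123 and 0.0881 with an estimated correlation). After the correction 29 were higher and 4 lower in X308, and 31 higher and 3 lower in R330, with medians of 0.58 and 0.75. The list passed overcorrected camera (adjusted p = 0.0106 and 0.00546), but not with an estimated correlation (adjusted p = 0.339 and 0.246). Antigen presentation rose, 14 of 20 with 2 lower in each, the same adjusted over the list alone (camera adjusted p = 6.54e-04 and 0.00143, adjusted p = 0.0698 and 0.0881 with an estimated correlation). The unfolded protein and integrated stress list rose, 19 of 30 with 7 lower and 21 with 7 lower (20 and 7, and 21 and 7 adjusted over the list alone; camera adjusted p = 0.00257 and 0.00143, adjusted p = 0.123 and 0.0881 with an estimated correlation). Cytosolic ribosomal protein genes, all 54 higher, and oxidative phosphorylation genes, 39 of 40 higher in each, had the same counts adjusted over the list alone and passed only with the preset correlation (adjusted p = 0.123 and 0.109, and 0.123 and 0.0881 with an estimated correlation), and the length and GC trend of these comparisons was as strong as against WT, with rho of -0.637 and -0.633 for length. The antigen presentation, unfolded protein, ribosomal and oxidative phosphorylation lists did not pass overcorrected camera in either form. Their corrected medians in X308 were 0.76, 0.31, 0.60 and 0.47, against 1.03, 0.66, 1.33 and 1.10 before. Those in R330 were 0.66, 0.30, 0.61 and 0.56, against 0.83, 0.58, 1.32 and 1.11. Estrogen response genes were lower in R330 than in 2R-A, with 12 of 40 higher and 23 lower (13 and 23 adjusted over the list alone). Their camera adjusted p was 0.0233, and 0.32 with an estimated correlation. They did not pass overcorrected camera (adjusted p = 0.363), with a corrected median of -0.30, against -0.38 before. After the correction 13 of 20 basal and myoepithelial genes were higher and 0 lower in each form (overcorrected camera adjusted p = 0.0106 and 0.00842, and 0.123 and 0.11 with an estimated correlation). Cholesterol synthesis genes, 18 and 17 of 24 lower after the correction, also passed overcorrected camera (adjusted p = 0.00716 and 0.00842, and 0.123 and 0.11 with an estimated correlation). The mitosis list passed overcorrected camera as higher (adjusted p = 0.00796 and 0.00192, and 0.67 and 0.547 with an estimated correlation). Its corrected values do not bear this out. By them 13 were higher and 15 lower in X308, and 15 higher and 12 lower in R330, with medians of -0.00492 and 0.0453. Corrected, mitochondrially encoded genes were lower, 11 and 12 of 13 (overcorrected camera adjusted p = 8.11e-04 and 6e-04, and 0.67 and 0.547 with an estimated correlation). Replication-dependent histones were then lower in R330, 11 of 18 with 2 higher (overcorrected camera adjusted p = 0.0215, and 0.134 with an estimated correlation).

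R330 and X308 were then compared with each other. Genes of the hypoxia response were lower in R330. CA9, carbonic anhydrase 9, was at 0.933 ± 0.103 CPM in R330 and 2.67 ± 0.266 in X308, a log2 fold change of -1.50 ± 0.25 (adjusted p = 0.00108). PPFIA4 was at -1.45 ± 0.10, NDRG1, a stress-response gene, at -1.14 ± 0.09 and MIR210HG, the host of a hypoxia-induced microRNA, at -1.03 ± 0.14. Of 32 hypoxia and glycolysis genes 12 fell and 0 rose, and 17 fell when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 7.8e-24, and 6.2e-04 with an estimated correlation). DNA replication and G1/S genes were higher in R330, 10 of 40 with 0 lower (24 and 1 adjusted over the list alone; camera adjusted p = 2.47e-20, and 0.00707 with an estimated correlation), as were mitosis genes, 3 of 35 with 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 2e-09, and 0.0387 with an estimated correlation). Luminal identity genes were lower, 5 of 29 with 0 higher (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 6.91e-05, and 0.0387 with an estimated correlation). After the length and GC correction 1 luminal gene was higher and 6 were lower, with a median of -0.04, against -0.07 before. The list did not pass overcorrected camera (adjusted p = 0.131, and 0.344 with an estimated correlation). In overcorrected camera the mitosis list passed only with the preset correlation (adjusted p = 6.54e-04, and 0.344 with an estimated correlation). The hypoxia and DNA replication lists passed there with both. R330 replicate 1 stood apart from the other R330 libraries, with a chi-square per degree of freedom of 5.27 and 5.30 against them and 1.95 between those 2. Without it the hypoxia and DNA replication lists passed in the same direction (camera adjusted p = 3.13e-23 and 1.44e-18).

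A further 8 lists passed between R330 and X308 only with the preset correlation. Heat shock genes were higher (5 of 18; 7 adjusted over the list alone; camera adjusted p = 5.52e-06, adjusted p = 0.0702 with an estimated correlation), and so were oxidative phosphorylation (2 of 40; camera adjusted p = 2.22e-05, adjusted p = 0.332 with an estimated correlation), interferon-response (1 of 40; camera adjusted p = 0.0412, adjusted p = 0.264 with an estimated correlation) and cholesterol synthesis genes (0 of 24; 2 adjusted over the list alone; camera adjusted p = 0.0425, adjusted p = 0.134 with an estimated correlation). Estrogen response genes (5 of 40 fell; 1 rose and 10 fell adjusted over the list alone; camera adjusted p = 1.08e-04, adjusted p = 0.0928 with an estimated correlation), immediate early genes (2 of 22; 4 adjusted over the list alone; camera adjusted p = 0.00277, adjusted p = 0.101 with an estimated correlation), NF-kB and inflammatory genes (0 of 21; 1 adjusted over the list alone; camera adjusted p = 0.0173, adjusted p = 0.0702 with an estimated correlation) and antigen presentation genes (0 of 20; camera adjusted p = 0.0323, adjusted p = 0.0928 with an estimated correlation) were lower. Of these 8, only the heat shock, oxidative phosphorylation and cholesterol synthesis lists passed overcorrected camera, again only with the preset correlation. Among the others, the interferon median went from 0.03 to 0.07 with the correction, with 4 members then called higher. Medians shrank for estrogen response (-0.04 to -0.02), immediate early (-0.09 to -0.03), NF-kB and inflammatory (-0.10 to -0.05) and antigen presentation genes (-0.09 to -0.05). By annotation terms, 13 of 63 genes of the proteasome complex were among those higher in R330 (adjusted p = 5.27e-09, hypergeometric test), 15 of 209 of RNA splicing (adjusted p = 2.3e-04) and 9 of 103 of DNA replication (adjusted p = 0.00331).

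In total 199 genes were higher and 163 lower in R330 than in X308, 4 and 11 of them at least 2-fold. The total of 362 was 214 without X308 replicate 2 and 525 with a block for the batch tag. The share that was higher, 55.0%, moved with the way of testing and with the libraries used, from 68.2% to 75.7% without single X308 or R330 libraries. DESeq2 called 490 higher and 74 lower, scaling by library totals 131 and 189, only the 2 groups compared 38 and 64, limma on FPKM 34 and 71, and the length and GC correction 710 and 233.

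The overlap of the 3 comparisons with WT was counted to find genes that all 3 mutants moved in one direction. It held 190 genes higher and 105 lower. Expected were 44.4 and 32.7 if all calls were independent, but X308 and R330 alone shared 6026 higher and 6305 lower genes. That reference is therefore too low. By pairs, 2R-A shared 199 higher genes with X308 where 117 were expected, and 107 lower where 81.5 were. With R330 it shared 195 higher where 114 were expected, and 111 lower where 82.6 were. All 3 comparisons share the WT libraries, and 3 are too few to split. In 20 simulated data sets without change 0 genes were shared by all 3 comparisons in either direction, and at most 1 by a pair. With no gene changed few calls arise, so this cannot show what overlap the shared WT libraries give at the real call rates. Part of the excess may come from the shared WT libraries. The covariance of fold changes of 2R-A with those of X308 and R330 exceeded that of the simulations by 0.0307 and 0.0291. Their correlation was lower than simulated, 0.164 and 0.160 against 0.489 and 0.487. So was the share with the same sign, 53.8% and 53.3% against 66.3% and 66.2%. Simulated correlations reflect the shared WT libraries alone. Real fold changes of X308 and R330 had standard deviations of 1.15 and 1.14, so correlations and shares are not alike measures here. For X308 with R330 the covariance was 1.26 against 0.0193 and the correlation 0.961 against 0.482. IFI44L, IFI44, IFI27 and OAS2 rose in all 3, OAS2 by 2.54 ± 0.08, 3.07 ± 0.08 and 3.04 ± 0.08 in 2R-A, X308 and R330 (corrected 2.55, 3.53 and 3.50). SGPP2, a phosphatase of sphingosine phosphate, was at -0.61 ± 0.12, -1.36 ± 0.14 and -1.59 ± 0.14 (corrected -0.60, -1.34 and -1.55), and ABCC4, an efflux pump, at -0.58 ± 0.10, -1.19 ± 0.11 and -1.12 ± 0.11 (corrected -0.55, -0.41 and -0.35). SLC7A11 was at -0.55 ± 0.07, -1.86 ± 0.09 and -1.44 ± 0.08 (corrected -0.52, -0.55 and -0.18, the last not called). Of the 302 genes that rose in 2R-A, 199 also rose and 67 fell in X308, and 195 rose and 69 fell in R330. Of the 206 that fell in 2R-A, 107 also fell and 73 rose in X308, and 111 fell and 73 rose in R330. The shared count of higher genes was 108 without WT replicate 1, 107 without WT replicate 2 and 112 without 2R-A replicate 3. The shared count of lower genes was 39 without WT replicate 1, 59 without WT replicate 2, 63, 61 and 52 without 2R-A replicates 1, 2 and 3, and 186 without R330 replicate 1.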

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

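The length and GC correction, library totals without TMM, and the correction together with the replicate block were chosen after the data had been seen, and the other alternatives before. Of 224 fold changes of named genes other than GATA3, which is given below, 9 changed direction under any alternative. Another count, of 37, is of those that changed direction or side of the threshold under at least 1 of the 28 alternatives chosen before. Changes of direction were counted only where the main test or the alternative called the gene. The totals for X308 and R330 against WT and against 2R-A stayed within 1.5 times under all alternatives except the filter on FPKM of at least 5, which leaves fewer genes to test. With the replicate block for the batch tag the totals were 643, 13243, 13158, 13213, 13069 and 525 in the order 2R-A, X308 and R330 against WT, X308 and R330 against 2R-A, and R330 against X308, and with the replicate block for the number in the title 616, 13199, 13124, 13186, 13048 and 475. Low counts limit genes near 1 CPM, where a few reads decide a fold change. For the changes below the cause was not tested.

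For 2R-A against WT the main count of 508 became 1010 with only the 2 groups compared, 334 with limma on FPKM, 313 with a pseudocount of 0.1, 246 without a filter, 311 with FPKM of at least 5, 284 on TPM, 337 with median-of-ratios scaling, 270 without a trend, 337 with robust limma, 936 with the length and GC correction, and 976 with that and the replicate block. Leaving out single libraries gave between 259 and 828. With FPKM of at least 5, the counts for X308 and R330 were 6963 and 6960 against WT and 6977 and 6927 against 2R-A, and 7176 genes differed among the 4 forms.

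For R330 against X308 the main count of 362 became 564 with DESeq2, 102 with only the 2 groups compared, 105 with limma on FPKM, 119 and 100 with pseudocounts of 0.1 and 5, 79 without a filter, 122 with FPKM of at least 5, 64 on TPM, 51 with quantile normalization, 65 without a trend, 102 with robust limma, 943 with the correction and 979 with that and the replicate block. Leaving out single libraries gave between 214 and 494.

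The log2 fold change of GATA3 in X308 against WT, 0.10, became -0.0933 with limma on FPKM, also without a filter, with FPKM of at least 5, without a trend and with robust limma, -0.0936 and -0.0917 with pseudocounts of 0.1 and 5, -0.399 on TPM, 0.0795 with median-of-ratios scaling, -0.840 with quantile normalization, -0.0931 with the correction, -0.0928 with that and the replicate block, -0.0938 with library totals, and between 0.0856 and 0.130 without single libraries. In R330, 0.20 became -0.00624 with limma on FPKM and the same 4 variants, -0.00627 and -0.00610 with the pseudocounts, -0.305 on TPM, -0.760 with quantile normalization, 0.0387 with the correction, 0.0381 with that and the replicate block, and -0.00426 with library totals. GATA3 passed as lower in X308 on TPM (limma adjusted p = 2.88e-05) and with quantile normalization (limma adjusted p = 7.23e-08). It also did with the correction (adjusted p = 0.0120), with that and the replicate block (0.00798) and with library totals (0.0422). In R330 it passed as lower on TPM (limma adjusted p = 2.67e-04) and with quantile normalization (limma adjusted p = 1.81e-07). R330 against X308 passed for GATA3 with DESeq2 (0.125), the correction (0.132) and that with the replicate block (0.131), and R330 against 2R-A lay between -0.146 and -0.0649 without single libraries.

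Among the other named genes, counted in that way, the sign changed in X308 for HOXC10 on TPM (-0.0190). With quantile normalization it changed in R330 for GAPDH (-0.0175) and CALR (-0.000701). With the correction alone and with the replicate block it changed in X308 for HOXC10 -0.0741 and -0.0734 and CORO1A -0.396 and -0.393, and in R330 for JUNB -0.00249 and -0.00269, SOX4 0.0446 and 0.0451, MT-ND6 -0.0351 and -0.0332, H2BC5 -0.138 and -0.139 and CORO1A -0.0326 and -0.0280.

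Of the 24 lists, the number past the threshold with the correlation estimated was 2 for X308 and 2 for R330 against WT, 0 and 0 against 2R-A and 4 for R330 against X308. With fry, which tests each list alone, it was 21 and 24 against WT and 23 and 23 against 2R-A, and without the low-count filter, which left 25 lists to test, 9, 10, 9 and 10. In overcorrected camera it was 3 for R330 against WT and 6 for R330 against X308, and 3 and 6 with the replicate block as well. In overcorrected camera with the correlation estimated it was 7, 0 and 1 for 2R-A, X308 and R330 against WT. It was 0 and 0 there against 2R-A, and 2 for R330 against X308.

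Genes higher in all 3 mutants, 190, became 125 with limma on FPKM, 81 without a filter, 124 with median-of-ratios scaling, 22 at 2-fold or more, 290 with the correction and the replicate block, and between 107 and 278 without single libraries. Genes lower in all 3, 105, became 47 with a pseudocount of 0.1, 50 without a filter, 68 with median-of-ratios scaling, 1 at 2-fold or more, 173 with the correction, 175 with that and the replicate block, and between 39 and 186 without single libraries.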

Other observations

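Markers of other cell types were counted in every library. The highest count of PTPRC, LAPTM5, TYROBP or LYZ, which leukocytes express strongly, was 4 in any mutant library and 7 in any WT library. ITGAM and CORO1A, which other cells also express, made up most of the summed leukocyte markers, which rose from 11.8 ± 0.707 CPM in WT and 9.88 ± 0.0877 in 2R-A to 17.04 ± 1.17 in X308 and 18.5 ± 0.653 in R330 (n = 3). After the length and GC correction CORO1A was at -0.40 in X308 and -0.03 in R330 against WT, the latter not called. Fibroblast and endothelial markers summed to 15.1 ± 0.884 in WT, 15.5 ± 1.68 in 2R-A, 11.7 ± 0.831 in X308 and 10.3 ± 1.24 CPM in R330.

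The subunits that recognise and unfold substrates for the proteasome stood out between R330 and X308. Of 21 genes of the proteasome accessory complex 9 were higher in R330 (adjusted p = 5.27e-09, hypergeometric test), and of 10 genes of the CMG helicase complex, which unwinds DNA at replication forks, 4 were higher (adjusted p = 0.00314). No term passed among genes lower in R330, of 3294 tested with edgeR calls.

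The tests below were chosen after the results were seen, except the 100 regroupings of the 12 libraries. For any difference among the 4 forms, 1 of 100 regroupings, the real one, gave as many genes, 13936 against at most 5 in the others. Libraries of a group were thus more alike than libraries grouped at random. A single culture or preparation per group would give this too, so the count does not speak for an effect of the forms. For pairs of groups, 10 splits of 6 libraries are too few for a share under 0.05. The real counts of genes were 508, 13217 and 13133 for 2R-A, X308 and R330 against WT, 13182 and 13049 against 2R-A, with 0 in any other split, and 362 for R330 against X308, with at most 1. In each of these 6 comparisons 1 split reached the real count. For lists past the threshold the real counts were 12, 5, 5, 5, 6 and 12 in the same order, the highest others 9, 6, 6, 6, 5 and 6, and 1, 6, 6, 5, 1 and 1 splits reached the real count. Lists thus also passed with the preset correlation in splits that mix the groups, so a pass with it alone is uncertain.

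Fold changes of X308 and R330 followed transcript length and GC content. Sequencing depth is argued against, since after thinning all libraries to 15813036 counts the weakest Spearman's rho with length was -0.631. Each batch tag of the labels holds 1 library of each group, so a shift shared by a tag cancels between groups. Between single libraries of a tag the weakest rho was -0.609 (n = 6 pairs), which adds little to that design. A difference in RNA integrity, library preparation or read handling between these groups and the others stays open. MT-ND4L counts per 100 MT-ND4 counts, which a shared message carries, averaged 2.47 in X308 against 12.1 in WT (n = 3 each). Exons of MT-ND4L overlap another gene, so its reads are uncertain. In CPM the shorter frames, MT-ND4L and MT-ATP8, were lower in all X308 and R330 libraries than in all others, and MT-ND4 and MT-ATP6 higher. Across coding genes shorter transcripts were higher instead. The ratios are therefore not a case of the same trend and do not show its source. Genomic span added 0.771% and 0.788% of variance in X308 and R330 to transcript length and GC content, transcript length added 10.9% and 11.4% to span and GC content, and across 306 single-exon genes rho with transcript length was -0.466 and -0.458. An effect of the GATA3 forms on whole messages by their length or GC content would leave the frames of one message in step. MT-ATP8 per 100 MT-ATP6 parted as well (21.8 in WT, 7.82 in X308 and 8.87 in R330). This argues against such an effect for these mitochondrial messages. For other genes it stays open, because each group is 1 construct and the labels do not say whether its libraries were prepared apart.

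Interferon-response genes were higher in all 3 mutants than in WT. The length and GC trend as the whole cause in X308 and R330 is argued against by list medians of 1.64 and 1.67 after the correction and 1.91 and 1.98 before (n = 40 genes), while in 2R-A both properties held only 0.697% of the variance, and leukocytes or their RNA are argued against by a highest count of 4 for their abundant transcripts in 9 mutant libraries. A state of the one culture or line behind each group, for example a response to infection or to the vector, cannot be told apart from an effect of the GATA3 forms, because each group holds 1 construct. The lowest 2R-A library lay 1.10 above the highest WT library in the list mean, as either would allow. A hypothesis is that WT GATA3 holds this program down and that the changed forms relieve it, which cells of an independent infection and an empty vector would test.

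Non-coding genes inside introns of coding genes fell 4-fold in X308 and R330 more often than those outside, although the median log2 fold change was -0.33 and -0.39 on the strand of the host and 0.03 and 0.06 on the opposite strand. A strand setting that discards one strand is argued against, since 25.5% of genes on the strand of their host fell 4-fold in X308 (72 of 282). After the correction the share was 33.0%, against 13.97% outside coding genes. The trend was fitted to protein-coding genes only, and the share outside rose too, from 9.15%. The correction therefore cannot decide whether the length and GC trend accounts for these falls. Fewer reads from unspliced RNA or genomic DNA in these libraries may account for part of these falls. Before the correction 19.5% of genes on the opposite strand (69 of 353) fell as well, against 9.15% outside coding genes. In a stranded library, unspliced RNA of the host bears on those genes only if the counting ignored strand, and the strand setting is not given. Odds ratios against genes outside were 3.40 (Fisher exact p = 5.6e-13) and 2.41 (p = 1.58e-07), over 3 libraries per group, and genes that overlap are not independent. Whether GATA3 forms change these transcripts themselves was not tested.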
